A study of Mus musculus with 6 samples.

How the data were processed

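RNA from testes of mice at postnatal day 9 was labelled with Cy3 and hybridised to NimbleGen long-oligonucleotide mouse expression arrays, with 1 sample on each array, per the labels. The deposited values are intensity on a linear scale, with 1 value per RefSeq transcript accession and array, and RMA is the processing tool named per the submitters' processing notes. RMA normally returns log2 values, so the deposited values were checked first: they ran from 8.81 to 65190, which is not a log scale, and log2 was therefore taken of the deposited intensity before any test, as the design fixed for that case. The version of RMA, its background correction and the probe annotation are not given in the sources used here. The quartiles of the 6 arrays were alike, and no further normalization was applied for the main results.

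The table held 25631 rows. RefSeq accessions were matched, without version numbers, to symbols of the annotation of assembly GRCm38.p6, which gave a symbol to 17780 rows (69.4%) for 17277 different genes. Of 18879 rows with an NM accession 17761 were named, against 19 of 6752 rows with an XM accession, so 7851 rows stayed unnamed here and were tested under their accession only. The build behind the array design is not given in the sources used here, so no coordinates are reported. For 433 genes with several rows, the row with the highest mean over all 6 arrays stood for the gene.

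Samples were grouped by their titles and genotype labels into 3 control (Cre-negative) and 3 Dmrt1 KO (Cre-positive) arrays. Replicate numbers follow the order of deposition and pair no samples. The start of the array number in each title split the arrays into 3 groups, which served as a possible batch: control replicate 1 and Dmrt1 KO replicate 1 in group 1, control replicates 2 and 3 and Dmrt1 KO replicate 2 in group 2, and Dmrt1 KO replicate 3 alone in group 3, so that a model with the group as a block gives that array no weight in the comparison. All per-sample columns were used.

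Each row was tested in limma (version 3.58.1, R version 4.3.3) with lmFit and eBayes on the log2 values of all 6 arrays, with no covariate and no filter, and p-values were adjusted by the Benjamini-Hochberg method over all rows with a threshold of 0.05. Errors of log2 fold changes are limma's moderated standard errors (SE), on 4 residual and 3.96 prior degrees of freedom. An exact permutation test of 3 against 3 arrays cannot give a two-sided p below 0.1, so none was used. Shifts of 21 gene lists (410 different genes, 366 measured) were tested with limma's camera with a preset correlation between genes of 0.01, adjusted over the lists, then again with an estimated correlation and with limma's fry. The test, the lists, the alternatives and the rule for named genes were fixed before the data were examined.

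The rule named 14 candidates known from work on Dmrt1 and spermatogonia, up to 12 rows in each direction with a gene name and no overlap between groups (those past the threshold by size of change, then those with the smallest limma p, said not to pass), and up to 4 members of each list with the smallest limma p. Nobox was left off the oocyte list by an error in writing it, so wherever it is given it was chosen after its values were seen.

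The tests were run on simulated data with the row means of these arrays and 200 changed rows among 25631, in 10 simulations. Row variances were drawn at random from the prior that limma fitted to these arrays, with normal and independent rows. The row test recovered 4.60% of 2-fold, 74.4% of 4-fold, 94.2% of 8-fold and 98.4% of 16-fold changes, with 4.84% false calls among all calls. In 100 simulations of the list test over 3000 independent rows, a list of 20 rows shifted by 1 on the log2 scale was called in 100% and an unshifted list in 3%. Independent rows leave out the correlation between genes of a real list. The simulated variances follow the model of the test, ignore intensity and give every array the same spread. The recovery and false call rates therefore need not hold for these arrays. The number of arrays limits the precision, and most 2-fold changes were missed in the simulation.

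The alternatives fixed in advance were quantile normalization, subtraction of array medians, leaving out the 50% of rows with the lowest mean, eBayes with trend and robust settings, no moderation, array weights, 1 row or the mean of rows per gene, the array number group as a block, each array left out in turn, looser thresholds, an estimated correlation and fry. Added after seeing the data were log2(value + 50), the Crisp1 level of each array as a covariate, leaving Crisp1 out of its list with and without that covariate, and leaving out the 3 arrays highest in Crisp1, which keeps 2 controls and 1 Dmrt1 KO array and estimates the spread from those controls alone. Figures were drawn with matplotlib version 3.10.9 in Python version 3.11.15.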

Results

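Gene expression was measured in testes of mice 9 days after birth, in 3 control arrays, whose samples were Cre-negative, and 3 Dmrt1 KO arrays, whose samples were Cre-positive in a Cre line that the labels call NGN-cre. Dmrt1 encodes a transcription factor of Sertoli cells and germ cells. Each array measured 25631 transcript accessions, of which 17780 could be named for 17277 genes. Median intensity per array ran from 498.1 to 543.8, and Pearson's r of log2 intensity between arrays, across rows that are not independent replicates, ran from 0.966 to 0.988. Dmrt1 KO replicate 3 stood apart, with no r above 0.973 to any other array, while no other pair fell below 0.978. Nothing in the labels says that the samples came from separate animals, so the p-values measure only the spread between these samples.

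The comparison asks which transcripts differ between conditionally targeted and control testes at this age. Cre status follows the groups, so an effect of Cre itself cannot be told apart from that of targeting Dmrt1. The targeted gene, Dmrt1, measured by accession NM_015826, was lower in every Dmrt1 KO array: its log2 intensity was 13.59, 13.49 and 13.21 in control replicates 1, 2 and 3 and 11.98, 12.08 and 12.27 in Dmrt1 KO replicates 1, 2 and 3. The difference was 2.50-fold (log2 fold change -1.32 ± 0.20, SE, n = 3 arrays per group), with a limma adjusted p of 0.124 over all rows. Within the array number groups that hold both genotypes the Dmrt1 difference was -1.61 in group 1 and -1.27 in group 2, and with the group as a block it was -1.42 with an adjusted p of 0.0955. Whether the Dmrt1 probes lie in the deleted part of the gene is not given in the sources used here, so the remaining signal cannot be read as remaining transcript from targeted or untargeted cells.

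The rows that passed the test in the Dmrt1 KO arrays were nearly all higher. Ap3b2, a subunit of the AP-3 vesicle adaptor found mostly in neurons, rose 12.2-fold (log2 fold change 3.61 ± 0.25, SE, limma adjusted p = 0.00842). Prmt8, an arginine methyltransferase known from brain, rose 11.9-fold (3.57 ± 0.34, adjusted p = 0.0312), and Crabp2, a cellular retinoic acid binding protein, rose 11.7-fold (3.55 ± 0.27, adjusted p = 0.00842). Nr5a2, a nuclear receptor active in ovarian granulosa cells and in pluripotent cells, rose 5.16-fold (2.37 ± 0.24, adjusted p = 0.0410). The secreted metalloprotease gene Adamts16 rose 4.82-fold (2.27 ± 0.19, adjusted p = 0.0127) and Mybphl, a myosin binding protein gene, rose 3.97-fold (1.99 ± 0.21, adjusted p = 0.0492).

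**Figure D1:**
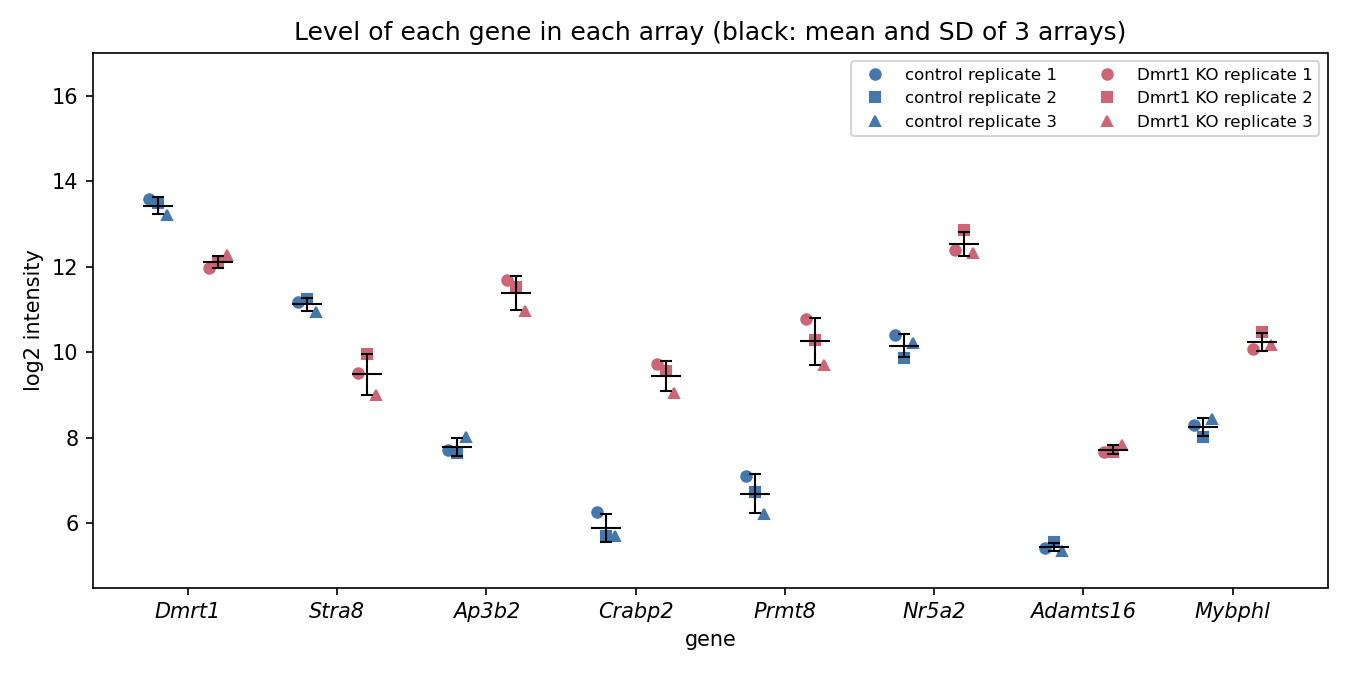
Log2 intensity (vertical axis) of 8 genes (horizontal axis) in each of the 3 control arrays (blue) and 3 Dmrt1 KO arrays (red), with the mean and SD of each group in black. The groups do not overlap for any of the genes shown, and Dmrt1 lay between 11.98 and 12.27 in the Dmrt1 KO arrays and between 13.21 and 13.59 in the controls.

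In all, 8 of the 25631 rows passed an adjusted p of 0.05, 7 higher and 1 lower in the Dmrt1 KO arrays. The 2 of them without a gene name were the accession XM_885629, which rose 6.63-fold (log2 fold change 2.73 ± 0.20, SE), and XM_900346, which fell by 1.91 ± 0.20 on the log2 scale. At an adjusted p of 0.1 the counts were 26 higher and 8 lower, and at an unadjusted p of 0.05 they were 1130 higher and 1306 lower. That balance turned with array medians subtracted (1295 higher and 1189 lower) and with the array number group as a block (1490 and 1293). It also turned without control replicate 1 (838 and 816) and without Dmrt1 KO replicate 3 (1504 and 1314). In 3931 rows (15.3%, where chance gives 10%) the groups did not overlap. Mean control levels of Crabp2 (5.89), Prmt8 (6.69) and Adamts16 (5.45) lay below 7.19, the 95th percentile of 1064 olfactory receptor rows used as a guide to background, so their folds depend on the scale: log2(value + 50), chosen after seeing the data, gave 6.80-fold for Crabp2, 8.27-fold for Prmt8 and 2.78-fold for Adamts16 (log2 fold change 1.48 against 2.27), against 10.1-fold for Ap3b2. Of the other genes that the rule named, 1 group mean lay under the guide for Dppa2, Fn3k, Nlrp5, Sox2, Fbxw13, Cyp26a1, Bmp2, Krt8, Prm1, Cd163 and Ccna1. The mean of XM_900346, the 1 lower row called, was also under it in the Dmrt1 KO arrays (6.06), so its difference depends on the scale too. Without control replicate 1, 2 or 3, or without Dmrt1 KO replicate 2, limma called 0 rows (806 to 1055 higher and 816 to 1250 lower at an unadjusted p of 0.05), without Dmrt1 KO replicate 1 it called 3 higher rows and none lower, and without Dmrt1 KO replicate 3 it called 44 higher and 3 lower. Quantile normalization gave 8 higher and 0 lower, and the array number group as a block gave 45 higher and 4 lower, including all 8 rows of the main test. Dmrt1 KO replicate 3 is alone in its array number group, so the block gives it no weight in the comparison and is in effect a further analysis without that array.

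Further genes were separated between the groups without passing the adjusted threshold. The pluripotency gene Dppa2 was 4.57-fold higher (3.15-fold with log2(value + 50), adjusted p = 0.0631), Tm4sf5 3.57-fold and Lctl 3.26-fold higher (both adjusted p = 0.0598), Fgl1 3.27-fold higher (0.0631), and Hoxb1, a homeobox gene, 2.72-fold higher (0.0830). Fn3k, a fructosamine kinase gene, was 4.11-fold higher (3.02-fold with log2(value + 50), 0.0830), and its other row gave a log2 fold change of 0.84 against 2.04. No named row passed in the lower direction. The nearest were Chrna7, a nicotinic acetylcholine receptor subunit (2.86-fold lower, adjusted p = 0.0830), Ifi204 (log2 fold change -1.32, 0.0830), Steap1 (3.34-fold, 0.0948) and Shc4 (3.12-fold, 0.0989). H1f10, Hddc3, Rnf138rt1 and Fbxw13 were 2.43-fold, 3.57-fold, 2.54-fold and 3.01-fold lower (Fbxw13 2.10-fold with log2(value + 50)), and B430306N03Rik and Nepn had log2 fold changes of -1.44 and -1.34, with adjusted p from 0.146 for H1f10 to 0.17 for Nepn. Both group means of Ifi204, B430306N03Rik and Nepn lay below the background guide, and with log2(value + 50) their log2 fold changes were -0.65, -0.74 and -0.65.

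Among the candidate genes for spermatogonial differentiation, Stra8, a retinoic acid responsive gene needed for meiotic entry, was 3.10-fold lower (log2 fold change -1.63 ± 0.27, SE, limma adjusted p = 0.147, and 0.0240 with the lowest 50% of rows left out), with all 3 Dmrt1 KO arrays below all 3 controls. Dmc1, a meiotic recombinase, was 2.20-fold lower (-1.14 ± 0.37, adjusted p = 0.40). Sohlh1, a transcription factor of spermatogonia, had a log2 fold change of 0.50 ± 0.20 (adjusted p = 0.508) and Sohlh2 of 0.29 ± 0.21. The receptor gene Kit gave -0.04 ± 0.22, Crabp1 -0.03 ± 0.19, Neurog3 0.11 ± 0.33, Gfra1 0.10 ± 0.24, Zbtb16 0.34 ± 0.25, Sycp3 -0.20 ± 0.26, Rarg 0.16 ± 0.30 and Cyp26b1 0.05 ± 0.22, all smaller than their errors except that of Zbtb16, which was 0.10 without control replicate 2. No row was named Dmrtb1, and that gene was not analysed here.

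Of 15 measured genes of the pluripotency network 12 lay above 0, with a median log2 fold change of 0.79 (camera adjusted p = 1.34e-08 with the preset correlation, and adjusted p = 0.163 with an estimated correlation). No member passed over all rows, and 7 were higher and 0 lower adjusted over the list alone, among them Dppa3, a germ cell and early embryo factor (5.83-fold), Dppa2, Dppa5a (2.91-fold), Pou5f1, a core pluripotency factor (2.67-fold), and Sox2 (2.22-fold, and 1.77-fold with log2(value + 50)). Fry's directional test gave an adjusted p of 0.0238. The median shift was 1.09, 0.75 and 0.56 in Dmrt1 KO replicates 1, 2 and 3, the last being the array that stood apart, and 0.99 and 0.68 within array number groups 1 and 2.

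The oocyte list gave a median of 0.19 over 21 measured genes (camera adjusted p = 0.0129, and adjusted p = 0.326 with an estimated correlation), and without control replicate 1 it was 0.08 (adjusted p = 0.0207). None passed over all rows, and 3 were higher and 1 lower adjusted over the list alone. The maternal effect genes Nlrp5 (8.23-fold higher, 6.09-fold with log2(value + 50), and 12.7-fold without Dmrt1 KO replicate 3, where it passed over all rows with an adjusted p of 0.00425) and Ooep (4.13-fold higher) were among them with Dppa3, which the pluripotency list also holds, while Nlrp14, a related gene of germ cells, was 2.58-fold lower. For granulosa cell genes of the ovary the median was 0.16 over 14 measured genes (adjusted p = 0.0490, and 0.326 as the adjusted p with an estimated correlation). Of these Nr5a2 rose, the only call both over all rows and adjusted over the list alone. Bmp2 had a log2 fold change of 1.27 ± 0.45 (SE, 1.03 with log2(value + 50) and 0.80 with the array number group as a block). Irx5, with both group means below the background guide, had one of -0.57 ± 0.24 (-0.23 with log2(value + 50)). Quantile normalization ended the granulosa call (adjusted p = 0.0723), as did leaving out control replicate 1 (0.154), control replicate 3 (0.125), Dmrt1 KO replicate 1 (0.272) or Dmrt1 KO replicate 3 (0.187). Without Dmrt1 KO replicate 1 the granulosa median was 0.07, and without Dmrt1 KO replicate 2 it was 0.26.

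Of 26 measured genes of meiotic prophase 22 lay below 0, with a median of -0.33 (camera adjusted p = 0.000488, and adjusted p = 0.326 with an estimated correlation). No member passed over all rows and 0 passed adjusted over the list alone. The genes with the smallest p were Hfm1, a meiotic helicase (log2 fold change -1.74 ± 0.52, SE), Msh5, a crossover factor (-1.23 ± 0.37), the meiotic cohesin gene Rec8 (-1.35 ± 0.43) and Dmc1. Without Dmrt1 KO replicate 3 Rec8 was -0.85. The median was -0.25 in array number group 1 and -0.28 in group 2, and -0.20 without control replicate 2 (adjusted p = 0.0196).

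Among 29 measured genes of undifferentiated spermatogonia the median was 0.11 (adjusted p = 0.0196, and adjusted p = 0.638 with an estimated correlation), and the call ended without Dmrt1 KO replicate 1 (adjusted p = 0.341) or control replicate 2 (0.116). The median was 0.06 without control replicate 2, 0.17 without control replicate 1 and 0.25 without Dmrt1 KO replicate 3. None passed over all rows, and Cdh1, the epithelial cadherin, was the 1 gene higher adjusted over the list alone (6.35-fold). Pou5f1 was 2.67-fold higher and Upp1 was 1.58-fold higher, and Thy1, a surface marker of these cells, had a log2 fold change of 0.59 ± 0.22 (SE). Pou5f1, Utf1 and Lin28a are also on the pluripotency list, and the median of the other 26 genes was 0.09. Genes of differentiating spermatogonia gave a median of 0.12 over 14 measured (adjusted p = 0.160), with 0 past the threshold over all rows and 1 higher, the homeobox gene Rhox10 (1.92-fold), and 1 lower, Stra8, adjusted over the list alone. For the general germ cell list the median was -0.12 over 21 measured genes (adjusted p = 0.447), with 0 calls over all rows or adjusted over the list alone. Tex19.1 in it had a log2 fold change of 0.55 ± 0.19 (SE).

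Genes of the retinoic acid pathway moved in both directions. Of 25 measured genes, Crabp2 passed over all rows, and 2 were higher and 2 lower adjusted over the list alone. Crabp2 and Dhrs3, a retinaldehyde reductase gene (log2 fold change 1.18, and 0.72 with log2(value + 50), both group means below the background guide), were the higher genes, and Stra8 and Cyp26a1, a retinoic acid degrading enzyme gene (2.36-fold lower, and 1.95-fold with log2(value + 50)), the lower ones. The list median was -0.13 (adjusted p = 0.140), and without Dmrt1 KO replicate 1 the list passed (-0.24, adjusted p = 0.0449). For the Dmrt family the median was -0.60 over 8 measured genes (adjusted p = 0.0196, and adjusted p = 0.326 with an estimated correlation), with 0 past the threshold over all rows and 3 lower adjusted over the list alone: Dmrt1 itself, Dmrta1 (1.82-fold) and Dmrtc1a (1.76-fold). The remaining rows of Dmrtc1a gave -1.06 and -1.37, and its values are uncertain because Dmrtc1b is nearly identical. Dmrtc1b is on the list too, as is the targeted gene, so the list call does not show a fall across the family. Dmrta2, with both group means below the background guide, had a log2 fold change of 1.02 ± 0.37 (SE, and 0.52 with log2(value + 50)). Without Dmrt1 KO replicate 3 the Dmrt family median was -0.20 (adjusted p = 0.135), with the array number group as a block, which gives the same array no weight, it was -0.23 (0.214), and without control replicate 1 it was -0.52 (0.0988).

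**Figure D2:**
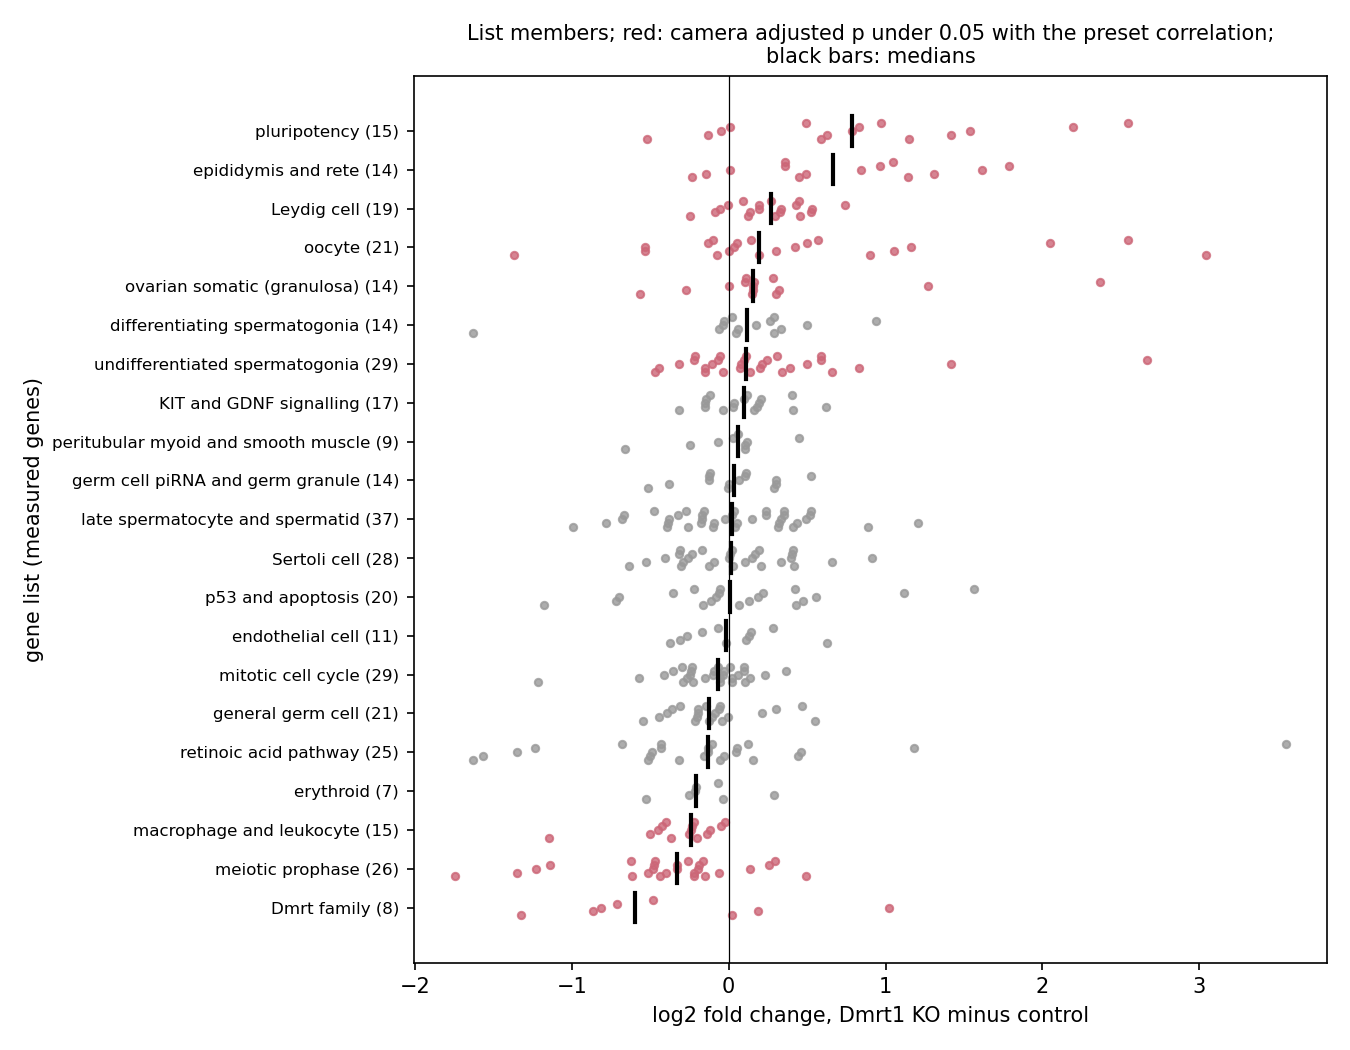
Log2 fold change of each measured gene (points; horizontal axis, Dmrt1 KO minus control) in the 21 lists (vertical axis, measured genes in brackets), with medians as black bars. Red lists passed camera's adjusted p of 0.05 with the preset correlation, among them the pluripotency list at a median of 0.79 and the meiotic prophase list at -0.33.

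Lists for other cell types were also measured. The epididymis and rete list marks the epididymis, which lies against the testis, and the rete, which is part of the testis. The list had a median of 0.67 over 14 genes (camera adjusted p = 0.000383, and adjusted p = 0.244 with an estimated correlation). None passed over all rows, and the keratin gene Krt18 (3.46-fold) and the transcription factor gene Pax8 (2.21-fold) were the 2 genes higher adjusted over the list alone. Krt19 had a log2 fold change of 1.05 ± 0.40 (SE) and Krt8 of 0.96 ± 0.41 (0.68 with log2(value + 50)). The list's median shift was 0.82, 1.01 and 0.11 in Dmrt1 KO replicates 1, 2 and 3. In control replicates 1, 2 and 3 it was 0.25, -0.33 and 0.02. Crisp1, a secretory gene of the epididymis, had a log2 intensity of 9.70, 4.11 and 6.49 in the controls, their mean being under the background guide, and 9.73, 10.96 and 4.46 in the Dmrt1 KO arrays. Within each group the list shifts ranked in the same order as Crisp1, which is itself on the list. With Crisp1 as a covariate, which fixes Crisp1 itself at 0, the list without Crisp1 had a median of 0.51 (camera adjusted p = 0.000494) against 0.49 with no covariate.

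**Figure D3:**
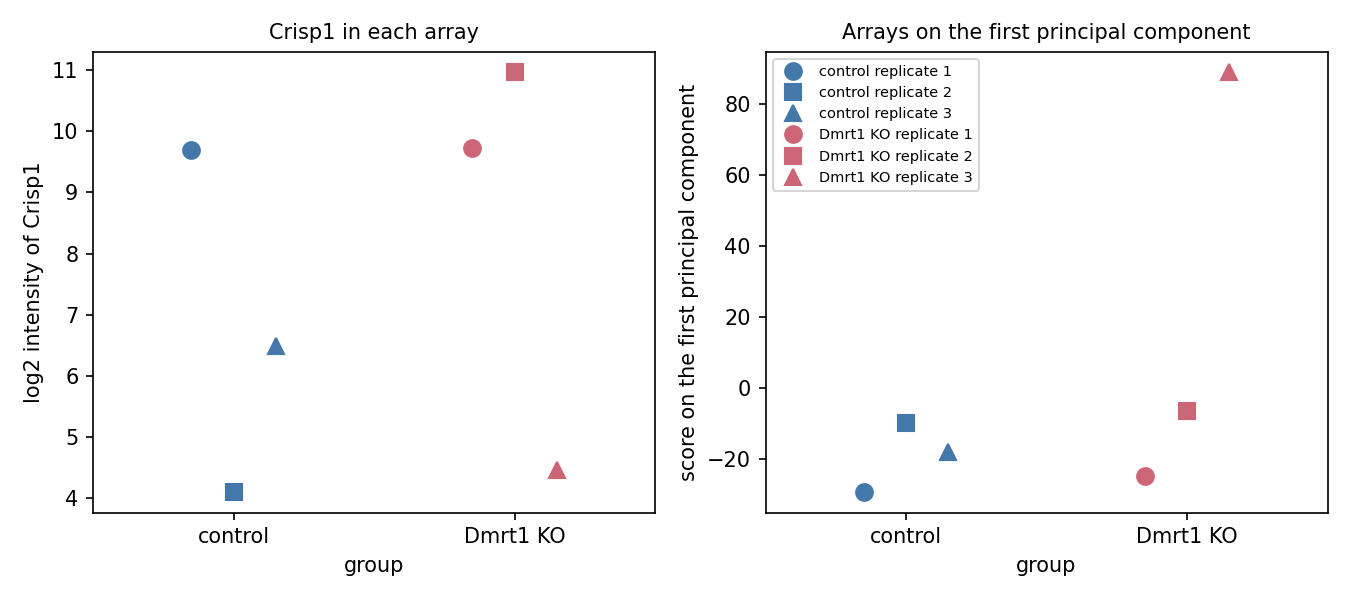
Log2 intensity of Crisp1 (left) and the score on the first principal component of all rows (right) for each control (blue) and Dmrt1 KO (red) array. Crisp1 ran from 4.11 to 10.96 with no split by group, and Dmrt1 KO replicate 3 had a score of 88.9 where the other arrays lay between -29.3 and -6.50 on a component holding 39.9% of the variance.

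Leydig cell genes had a median of 0.27 over 19 measured genes (adjusted p = 0.0102, and adjusted p = 0.244 with an estimated correlation), and the call ended without Dmrt1 KO replicate 3 (adjusted p = 0.0674) and with the array number group as a block (0.0709), which gives the same array no weight. The steroidogenic genes Hsd17b3 and Cyp17a1 gave 0.45 ± 0.20 and 0.52 ± 0.26 (SE), the latter 0.25 without control replicate 2. All 15 measured macrophage and leukocyte genes lay below 0, with a median of -0.24 (adjusted p = 0.00940, and adjusted p = 0.309 with an estimated correlation). The scavenger receptor gene Cd163 gave -1.15 ± 0.30 (-0.80 with log2(value + 50)) and the complement gene C1qa -0.50 ± 0.25 (-0.27 without Dmrt1 KO replicate 3). In both lists 0 genes passed over all rows or adjusted over the list alone.

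The Sertoli cell list had a median of 0.02 over 28 measured genes (adjusted p = 0.760), with Ptgds at 0.91 ± 0.28 (SE), Trf at 0.66 ± 0.20 and Nr0b1 at -0.64 ± 0.24. Peritubular myoid and smooth muscle genes (9 measured) had a median of 0.06, a mean of -0.01 and a downward test (adjusted p = 0.914), with Lmod1 at -0.66 ± 0.23. Endothelial genes (11 measured) had a median of -0.02, a mean of 0.01 and an upward test (adjusted p = 0.915), with Pecam1 at 0.62 ± 0.23. Late spermatocyte and spermatid genes (37 measured) had a median of 0.02 and a downward test (adjusted p = 0.988), with Izumo1 at 1.21 ± 0.28, Prm1 at -0.78 ± 0.25 (-0.55 with log2(value + 50)) and Ybx2 at -0.68 ± 0.25. Many genes of that list, such as Akap4, Smcp and Adam2, had both group means below the background guide. Others, such as Odf2 and Ddx25, lay far above it. The erythroid (7 measured) median was -0.21 (adjusted p = 0.489), the germ cell piRNA and germ granule (14 measured) median 0.03 (0.811) and the KIT and GDNF signalling (17 measured) median 0.10 (0.265, and 0.0312 with a median of 0.35 without Dmrt1 KO replicate 2), with Spry4 at 0.62 ± 0.20. Mitotic cell cycle genes (29 measured) had a median of -0.07 (0.160), with Ccne2 at -1.22 ± 0.36 and Bub1 at -0.58 ± 0.22. In each of these lists 0 genes passed over all rows or adjusted over the list alone. The p53 and apoptosis list (20 measured) had a median of 0.01 (0.746) and 0 calls over all rows, while the cell cycle inhibitor gene Cdkn1a was higher (2.95-fold) and the nuclease gene Aen lower (2.26-fold) adjusted over the list alone.

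Of the 21 lists 9 passed with the preset correlation and 0 with an estimated correlation, while fry called 1 list directionally and 10 for change in either direction.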

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

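The alternatives with log2(value + 50) or Crisp1, and the choice of the Crisp1 arrays, were made after seeing the data. Only 3 arrays per group limit every count below, and dim rows near background weigh on the folds. Why a value moved was not tested. Leaving out the lowest 50% of rows tests fewer rows, but it also moved the unadjusted limma p, for Dmrt1 from 0.000193 to 1.78e-05. No moderation was not run for the lists, since camera has no such setting, and 1 row per gene is already the lists' main setting. No analysis paired by replicate number was possible because the labels give none, and the array number groups, which are not pairs, served as a block. Dmrt1 KO replicate 3 is alone in its array number group, so the block gives it no weight, and what the block changes cannot be told apart from leaving out that array.

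Against 7 rows higher and 1 lower, the counts were 35 and 17 with the lowest 50% of rows left out (fewer rows tested), 53 and 28 with trend and robust settings, 0 and 1 with no moderation (limma without moderation, 994 and 1117 at an unadjusted p of 0.05), 48 and 12 with array weights, and 45 and 4 with the array number group as a block. They were 8 and 0 with quantile normalization, 10 and 1 with array medians subtracted, 10 and 0 with 1 row or the mean of rows per gene, 11 and 1 with log2(value + 50), 7 and 0 with Crisp1 as a covariate, 26 and 8 at an adjusted p of 0.1, and 375 and 339 at an unadjusted p of 0.01 with a 1.5-fold change. Without the 3 arrays highest in Crisp1, which leaves 2 controls and only Dmrt1 KO replicate 3, the array that stood apart, they were 667 and 464. There the spread comes from the controls alone, on 1 residual degree of freedom, so neither these counts nor the list calls under that setting show a dependence on Crisp1. Leaving out each array gave 0 to 44 higher and 0 to 3 lower, with 0 of either without any control or Dmrt1 KO replicate 2, 3 and 0 without Dmrt1 KO replicate 1, and the highest without Dmrt1 KO replicate 3.

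Dmrt1 passed with the lowest 50% of rows left out (-1.32, adjusted p = 0.0190), trend and robust settings (-1.32, 0.00314) and array weights (-1.40, 0.0285), where the range over all its alternatives was 0.00314 to 0.561. Of the named genes 11, 20 and 16, Dmrt1 among them, gained a call under these settings, and Stra8 did under the first (-1.63, 0.0240) and the second (-1.63, 0.0102). In the same way 6 gained a call with the array number group as a block and 8 without Dmrt1 KO replicate 3. Nlrp5 was among them in both (3.62, 0.00523 and 3.67, 0.00425). Under none of the other settings for which gained calls were counted did more than 4 named genes gain one. The looser thresholds and the setting without the 3 arrays highest in Crisp1 were left out of that count. All 6 called named genes lost their call with no moderation and without any control or Dmrt1 KO replicate 2, 4 did without Dmrt1 KO replicate 1, and 1, Mybphl, with Crisp1 as a covariate.

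With an estimated correlation no list was called: pluripotency 0.79, epididymis and rete 0.67, meiotic prophase -0.33, macrophage and leukocyte -0.24, Leydig 0.27, oocyte 0.19, undifferentiated spermatogonia 0.11, Dmrt family -0.60 and granulosa 0.16, medians that do not change with the test. The epididymis and rete median was 1.09 and the oocyte median 0.50 with the lowest 50% of rows left out. With fry's directional test, which tests against no change and not against other genes, all of these but the pluripotency list lost their call. Its test for change in either direction called pluripotency, undifferentiated spermatogonia, epididymis and rete, granulosa, oocyte and Dmrt family. That test also called lists that camera did not: retinoic acid (fry adjusted p = 1.26e-05), differentiating spermatogonia (0.000435), Sertoli (0.0023) and p53 (0.0023). Without the 3 arrays highest in Crisp1 the calls ended for undifferentiated spermatogonia (0.10), Leydig (0.40), macrophage and leukocyte (-0.23), epididymis and rete (0.34), granulosa (0.15), oocyte (0.038) and the Dmrt family (-0.91), and the pluripotency median, still called, was 0.43. With Crisp1 as a covariate the undifferentiated list lost its call (0.043). With the array number group as a block Leydig (0.20), granulosa (0.10) and Dmrt family (-0.23) did, and granulosa also with quantile normalization (0.16), array medians subtracted (0.19) and array weights (0.083). With Crisp1 left out of it the epididymis and rete list stayed called, at 0.49 with no covariate and 0.51 with Crisp1 as a covariate. The p53 list gained a call with the lowest 50% of rows left out (0.16, adjusted p = 0.0473, of a range up to 0.940), as did KIT and GDNF signalling without Dmrt1 KO replicate 2 (0.35, 0.0312) and retinoic acid without Dmrt1 KO replicate 1 (-0.24, 0.0449).

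For genes the value, and for lists the test, turned direction for these, none of which passed as reported: with array weights Kit (0.041), Gfra1 (-0.0072), Sycp3 (0.040), Cyp26b1 (-0.069) and Sertoli (-0.036); with the block Kit (0.084), Gfra1 (-0.060), Sycp3 (0.072), Cyp26b1 (-0.12), general germ cell (-0.063, test upward) and Sertoli (-0.037); with Crisp1 as a covariate Neurog3 (-0.032), Crabp1 (0.015), late spermatocyte (-0.031, test upward) and endothelial (-0.11). With array medians subtracted Crabp1 was 0.0019, with log2(value + 50) late spermatocyte was 0.011 (test upward), and with the lowest 50% of rows left out peritubular was 0.025 (test upward). Without the 3 arrays highest in Crisp1 these were late spermatocyte 0.046, piRNA -0.12, peritubular -0.14, endothelial -0.16 and p53 -0.087. Where the test kept its direction, list medians changed sign 13 times with 1 array left out, in the ranges below, and 14 times in 6 lists otherwise, among the latter KIT and GDNF signalling with array weights (-0.040) and the block (-0.054), endothelial with the lowest 50% of rows left out (0.12), late spermatocyte with array weights (-0.14) and peritubular with the block (-0.052).

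Leaving out each array gave ranges of -0.16 to 0.086 for Kit, -0.13 to 0.41 for Neurog3, -0.085 to 0.24 for Gfra1, -0.42 to 0.0043 for Sycp3, -0.10 to 0.043 for Crabp1, -0.075 to 0.35 for Rarg, -0.093 to 0.17 for Cyp26b1, 0.096 to 0.48 for Zbtb16, 0.16 to 0.38 for Sohlh2, 0.25 to 0.68 for Cyp17a1, -0.62 to -0.27 for C1qa, -1.74 to -0.85 for Rec8, 0.69 to 1.49 for Krt19 and -0.77 to -0.38 for Irx5. For list medians it gave -0.050 to 0.14 for p53, 0.61 to 0.95 for pluripotency, 0.48 to 0.85 for epididymis and rete, -0.34 to -0.18 for macrophage and leukocyte, 0.084 to 0.24 for oocyte, -0.42 to -0.20 for meiotic prophase, 0.061 to 0.25 for undifferentiated spermatogonia, -0.24 to -0.098 for retinoic acid, -0.091 to 0.055 for late spermatocyte, -0.082 to 0.14 for piRNA, -0.14 to -0.095 for general germ cell, -0.051 to 0.10 for Sertoli, 0.20 to 0.36 for Leydig, -0.083 to 0.14 for peritubular, -0.090 to 0.10 for endothelial, -0.26 to 0.036 for erythroid, 0.072 to 0.26 for granulosa, -0.83 to -0.20 for Dmrt family and 0.0010 to 0.35 for KIT and GDNF signalling.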

Other observations

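The tests of gene families, germ cell share, spermatogonial share, epididymal carry-over, array batch and noise in the third intensity class were chosen after the results they bear on were seen, and those of a wrong label, of noise judged in the brightest class and of other splits before their results were seen. Hox, histone and Y-linked genes are families chosen for their values, so no p-value is given for them. Of 38 measured Hox genes 28 lay above 0, with a median log2 fold change of 0.45 (0.45 with quantile normalization and 0.48 with array medians subtracted). In 15 of them both group means lay below the background guide. Hoxb3 was 2.19-fold and Hoxb6 2.10-fold higher, and Hoxc13 was 1.97-fold lower (1.97-fold, 1.73-fold and 1.64-fold with log2(value + 50)), with 1 group mean of Hoxb6 and of Hoxc13 under that guide. Of 53 clustered histone genes 40 lay below 0, with a median of -0.25 (-0.24 and -0.22 under the same scalings), among them the testis histone genes H2bc1 (5.68-fold lower) and H2ac1 (2.36-fold lower), whose means in the Dmrt1 KO arrays lay below the background guide (3.13-fold and 1.83-fold with log2(value + 50)). In 8 of the histone genes both group means lay below it. Many clustered histone genes are nearly identical, so single values are uncertain and the rows may not be separate measurements. Without Dmrt1 KO replicate 3 the medians were 0.70 for Hox and -0.33 for histone genes. None of the genes named here passed over all rows.

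Other genes were also chosen after their values were seen. Nobox, an oocyte transcription factor gene, was 4.98-fold higher (log2 fold change 2.32 ± 0.33, SE, limma adjusted p = 0.0948), and Dnmt3l, a germ cell cofactor of DNA methylation, 2.35-fold higher (adjusted p = 0.185). All 5 measured Dppa genes lay above 0, also under both scalings, 1 of them with both group means below the background guide. The 8 measured Y-linked genes of the Ssty, Sly and Gm families, whose values are uncertain because their copies are nearly identical, had a median of -0.88, with all 8 below 0 except under subtraction of array medians, where 1 lay above 0, and 2 of them had both group means below the background guide. They are not 8 separate measurements, as the estimated correlation between them was 0.70. The controls varied more than the Dmrt1 KO arrays in all 8 (for Ssty1 an SD of 1.00 against 0.34).

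The pluripotency list passed as higher in the Dmrt1 KO arrays with the preset correlation, but not with an estimated correlation (adjusted p = 0.163). A larger share of germ cells of every kind would raise the general germ cell list as much if bright and dim rows respond alike. That was not tested. Control means ran from 9.67 (Dnd1) to 15.1 (Taf7l) in that list, against 6.22 for Dppa2 and 13.26 for Lin28a of the pluripotency list. The pluripotency shift exceeded that of the general germ cell list by 0.90 ± 0.22 (SD over 3 Dmrt1 KO arrays, which leaves out the spread between controls). It exceeded that of the undifferentiated spermatogonia genes not shared with it by 0.74 ± 0.13. That argues against a larger share of those cells as the whole cause only as far as the median of these genes tracks them. They leave out the shared genes Pou5f1, Utf1 and Lin28a. Some of them, such as Pax7 and Lhx1, had both group means below the background guide. With Crisp1 as a covariate, for epididymal carry-over, the pluripotency median was 0.78 against 0.79 without. It was 0.43 without the 3 arrays highest in Crisp1, where only Dmrt1 KO replicate 3 is set against 2 controls. A change of these genes within germ cells of the Dmrt1 KO testes, or a cell type outside these lists, may remain as a hypothesis, found on the same 6 arrays and not tested, for which sorted germ cells would be needed.

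The epididymis and rete list too passed as higher with the preset correlation only (adjusted p = 0.244 with an estimated correlation). With Crisp1 as a covariate the median of Krt8, Krt18, Krt19, Pax2 and Pax8 was 1.03 ± 0.30 against 1.05 before. That SE is over the 5 genes and measures no spread between samples. Krt18 (1.56 ± 0.21, limma SE) and Pax8 (1.06 ± 0.22) stayed higher, which argues against carry-over, as Crisp1 tracks it, as their whole cause. Krt8 gave 1.03 ± 0.43 and Krt19 moved from 1.05 to 0.79 ± 0.29. Pax2 was not higher before (0.01) or with the covariate (-0.24). For the 8 other secretory genes the median was 0.42 ± 0.13 against 0.41, too near the bound of 0.4 set for the test to decide. That median hides moves both ways: the covariate lowered Lcn2 (1.31 to 0.80), Defb2 (0.84 to 0.51) and Adam7 (0.49 to 0.25). It raised Lcn8 (0.36 to 0.66). Epididymal carry-over thus stays open for the secretory genes. Crisp1 may track the epididymis and not the rete, which is part of the testis. A differing share of rete thus stays open with another change in the testis itself.

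Dmrt1 KO replicate 3 stood apart from the other 5 arrays. Of the 47 rows called without it, 68.1% had a value in it nearer the other Dmrt1 KO arrays and the rest nearer the controls. That share lies between the bounds set for a wrongly labelled control and for a knockout, so it does not decide. Its Dmrt1 level of 12.27 lay below every control. Ap3b2 and Crabp2 had the smallest limma p without it. Its values for them, 10.96 and 9.05, lay above every control (at most 8.01 and 6.27). For these genes the values argue against a wrongly labelled control. The deviation of Dmrt1 KO replicate 3 from the other arrays was 1.30, 1.55, 1.42 and 1.14 times the next largest in 4 equal classes of rows from dim to bright. The excess in the third class, 7.43 SD above the other arrays and above the median row, argues against noise at dim rows alone, while that in the brightest stayed under the bound set for it. It is the only array (1) of its array number group, so a separate array batch cannot be told apart from that sample.

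With 3 arrays against 3 there are 10 splits, too few for a share under 0.05. The real split gave 8 rows past the threshold, and the highest other split gave 1. It gave 9 gene lists past the threshold with the preset correlation, against 5 for the highest other split. In both counts 1 of the 10 splits, the real one, reached the real value.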
